A study of Mus musculus with 48 samples.

How the data were processed

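Small RNA was sequenced from 48 libraries of C57BL/6 mice. Lavage fluid, lavage cell pellets and serum each had 3 untreated, 4 immunized and 7 allergic libraries, and epithelial brushings had 1, 2 and 3. Per the labels' protocols, immunized and allergic mice had weekly injections of 50 ug ovalbumin with alum. From 7 days after the last injection they were given saline or ovalbumin by oropharyngeal aspiration on 3 days. Lavage used 1 ml of saline, spun at 500 g for 5 minutes to part fluid from cells. Libraries were built from 20 to 65 ng of RNA with 5 random nucleotides on the 3' adapter. The labels do not say whether libraries with the same number in different compartments came from the same mouse, so p values measure only the spread between these libraries.

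The expected counts were deposited by the authors in 3 tables, 1 for each library set (2, 3 and 4), with reads that fit several entries split into fractions. Adapter trimming with cutadapt and the mm10 build are stated per the submitters' processing notes, without versions, and the aligner is not given in the sources used here. The deposited RPM values, a single table of all libraries, were made with DESeq2 per the submitters' processing notes; each column adds up to 1000000, and the lowest value of a library, 0.16 to 16.6, is shared by all its entries without counts. The count tables held 1409 entries. Of these, 113 were hairpins (0.017% of the counts) and 26 joined several mature names (1.57% of the counts), and 11 were not in the RPM table. The analysis plan had assumed whole counts, but 4.4% of the values were not whole. Expected counts were therefore rounded, which changed library totals by a median of 0.0079%, and then tested as planned. Counts are per mature sequence, so a miRNA made from several genes is not resolved to a gene. Positions of miRNA genes are from the GENCODE annotation of the mm10 assembly, 1-based.

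Every column matched a labelled library (0 unmatched). Untreated libraries were all in set 2, immunized libraries in sets 3 and 4, and allergic libraries in all of them. Non-allergic means untreated and immunized together. The library set was a term in every fit of allergic, untreated and immunized libraries, so that allergic libraries were compared within their sets. Allergic against untreated rests on set 2 and allergic against immunized on sets 3 and 4, while immunized against untreated is linked only through the allergic libraries. The samples, designs, tests, lists, alternatives and rule for naming miRNAs were fixed before the data were examined.

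Each comparison was fitted with edgeR 4.0.16 in R 4.3.3. Low counts were filtered with filterByExpr at a minimum count of 10, libraries were scaled by TMM, and dispersions were robust. Adjusted p values of single miRNAs are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a miRNA passed, or was called, at an adjusted p under 0.05. A fold change is allergic over the other group, or fluid over the other compartment, and its SE is the log2 fold change over the root of the F statistic. CPM values are TMM-scaled counts per 1000000, scaled within a compartment or, for the comparison of compartments in non-allergic mice, over all of them. They can add up to more than the total, and values of the same group differ a little between these scalings. Differences of allergic changes between compartments were tested as interactions in a joint fit. Where a group had 0 counts, the fold is given as a bound against a floor of 3 counts over the group. Such floors, and the CPM worth of 3 counts, cover counting error only.

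The named miRNAs are the 10 highest and 10 lowest log2 fold changes among those that passed, with a mean of at least 50 CPM. In the comparisons of allergic with non-allergic mice the same sign was also required in each library set. The other comparisons name 5 and 5. Members of a list may also be named, and where fewer than 3 passed, the 3 lowest p values are named as not passing. Fixed lists were hematopoietic (14 miRNAs), epithelial (15), multiciliated (7), erythroid (7), endothelial (2), mesenchymal and muscle (12), liver (4), activation-induced (11), the miR-17-92 family (12), the miR-23-27-24 clusters (8), the let-7 family (9) and the miR-30 family (5). The hematopoietic and activation-induced lists share miR-155-5p, miR-146a-5p and miR-147-3p. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation. Benjamini-Hochberg adjustment was over all 47 lists of the comparisons of allergic with non-allergic mice, and over the lists of each other comparison. List members were also adjusted over the list alone. Of the 47 list tests 17 passed with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.4675, and 16 passed with fry.

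Shares of a list are percents of the total count of a library, on a log2 scale after adding 0.001 percent. Likeness of a fluid library to another compartment is Spearman's rho with the mean profile of that compartment. Both were tested by exact 2-sided permutation of the group labels within library sets (720 permutations, smallest p 0.00278), adjusted by Benjamini-Hochberg over 9 and 3 tests. For brushings 8 permutations exist and the smallest p is 0.25. Shares and likeness used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

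Alternatives were DESeq2 1.42.0, DESeq2 size factors, total count scaling, no filter, no term for the set, a replicate block, limma on the deposited RPM values as log2 of the value plus 1, and leaving out each library. For shares and likeness they were another added constant, permutation over all libraries, Pearson's r and a reference of non-allergic libraries. Added after seeing the data were a fit of brushings of sets 3 and 4 only, the log2 CPM of miR-451a as a covariate, thinning of every library to 43083 counts, and a bound on RNA of lavage cells in fluid from miRNAs not under test. Replicate numbers were not taken to pair libraries. Calibrators added at ligation per the labels were not used here, so all values are relative to the total of a library's miRNA counts.

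The steps were tested on simulated data drawn from the means and depths of the real libraries, with 200 changed miRNAs. The spread was not taken from the real libraries. A single dispersion of 0.15 was used for every miRNA, with no difference between library sets, so the percents hold for that spread only. Of the changed miRNAs that passed the filter, those changed 2-fold were called in 66.7% of cases and those changed 4-fold in 100% for fluid (253 miRNAs tested), 63.2% and 100% for lavage cells (223 tested), 68.4% and 100% for serum (360 tested) and 18.2% and 76.2% for brushings (301 tested), in the comparison of allergic with non-allergic mice. For immunized against untreated mice these were 0% and 38.1% in fluid (302 tested), 0% and 27.8% in lavage cells (248 tested) and 2.94% and 48.5% in serum (428 tested).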

Results

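Small RNA libraries were compared from lavage fluid, lavage cell pellets, serum and lung epithelial brushings of C57BL/6 mice, to follow extracellular miRNAs of the airway lining fluid and blood beside those of the cells of the airway during an allergic response. Lavage fluid, lavage cells and serum each had 14 libraries. Of these 3 were of untreated mice, 4 of mice immunized by injection of ovalbumin with alum and then given saline into the airway, and 7 of allergic mice, immunized the same way and then given ovalbumin into the airway. The brushings had 6 libraries, 1 untreated, 2 immunized and 3 allergic, each from RNA of 1 to 3 mice. Untreated and immunized libraries together are called non-allergic. Levels and changes are relative to the other miRNAs of a library and are not amounts. Total miRNA counts were 135707 to 561803 per library in lavage fluid, 43087 to 960796 in lavage cells, 137638 to 2738223 in serum and 113004 to 654157 in brushings. At these depths 3 counts corresponded to 5.34 to 22.1 counts per 1000000 (CPM) in fluid, 3.12 to 69.6 in cells, 1.1 to 21.8 in serum and 4.59 to 26.5 in brushings. miR-21a-5p was the most abundant entry in all 14 fluid libraries, with 7.879% to 22.02% of the counts, and miR-451a, a red blood cell miRNA, was the most abundant in all 14 serum libraries, with 19.68% to 64.83%.

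Without allergy, lavage fluid carried the miRNAs of the airway epithelium at levels close to those of the brushings, far more than serum and more than lavage cells. miR-34c-5p, a miRNA of multiciliated cells, was at 18798 ± 4228 CPM in fluid (mean ± SD, n = 7). It was at 29981 ± 7888 in brushings (n = 3), 3993 ± 3490 in lavage cells (n = 7) and 62.8 ± 61.2 in serum (n = 7). miR-200c-3p, of the epithelial miR-200 family, was at 13176 ± 3499 CPM in fluid, 15279 ± 1475 in brushings, 3269 ± 948 in cells and 254 ± 129 in serum. miR-451a went the other way, with 7712 ± 4352 CPM in fluid, 2933 ± 1926 in brushings and 672046 ± 447587 in serum. The myeloid miRNA miR-223-3p was at 922 ± 533 CPM in fluid, 666 ± 54.7 in brushings, 16575 ± 6736 in cells and 15684 ± 11297 in serum.

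Against serum, 274 of 356 tested miRNAs differed in non-allergic fluid, 126 higher and 148 lower. The 6 measured multiciliated miRNAs were all higher, led by miR-34b-5p at 462-fold (log2 8.85, SE 0.48, edgeR adjusted p = 5.59e-15), miR-34c-5p at 402-fold and miR-449a-5p at 363-fold. The airway epithelial miR-135b-5p was 586-fold higher (log2 9.19, SE 0.48, edgeR adjusted p = 2.96e-15). Of the 14 measured epithelial miRNAs 13 were higher, and miR-203-3p was not called (log2 -0.18). All 5 erythroid entries were lower (miR-486a/b-5p log2 -7.28, miR-451a log2 -6.31), as were all 12 of the miR-17-92 family, all 4 liver miRNAs (miR-122-5p log2 -5.14) and both endothelial miR-126a strands. Of the 14 hematopoietic miRNAs 10 were lower (miR-150-5p log2 -4.69) and 2 higher, miR-181a-5p and miR-181b-5p. The let-7 family had 7 higher and 1 lower of 9, the miR-30 family 4 higher of 5, the miR-23-27-24 clusters 3 higher and 1 lower of 8 (0 lower adjusted over the list alone). The activation-induced list had 3 higher and 6 lower of 11 and the mesenchymal and muscle list 3 higher and 4 lower of 10. The other list counts were the same adjusted over the list alone. By camera the epithelial (adjusted p = 3.25e-08; adjusted p = 0.184 with an estimated correlation) and multiciliated lists (adjusted p = 1.26e-05; adjusted p = 0.184 with an estimated correlation) led.

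Against lavage cells, 243 of 356 miRNAs differed in fluid, 135 higher and 108 lower. The liver miRNA miR-122-5p had 280 counts in the 7 fluid libraries and 0 in the 7 cell libraries, at least 39.9-fold higher against a floor of 3 counts over the group. The fibroblast and muscle miRNA miR-199b-5p was 47.6-fold higher (log2 5.57, SE 0.59, edgeR adjusted p = 7.72e-09), miR-199a/b-3p was higher too (log2 4.32, SE 0.42), and 8 of 10 mesenchymal and muscle miRNAs were higher. All 14 epithelial and all 6 multiciliated miRNAs were higher in fluid, and 12 of 14 hematopoietic, 10 of 12 miR-17-92 and all 5 erythroid entries were lower. These counts were the same adjusted over the list alone. Those furthest below the cells included miR-511-3p (log2 -6.09, SE 0.49), from an intron of the macrophage mannose receptor gene Mrc1, and miR-764-5p (log2 -6.64), miR-1264-5p and miR-1298-5p, all from introns of Htr2c on chromosome X. The epithelial list had a camera adjusted p = 2.69e-05 (adjusted p = 0.259 with an estimated correlation) and the hematopoietic list 2.69e-05 (adjusted p = 0.213 with an estimated correlation).

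Against brushings, 40 of 356 miRNAs differed, 20 higher and 20 lower. Muscle miRNAs were lower in fluid, with miR-133a-3p at log2 -4.20 (SE 1.06, edgeR adjusted p = 0.0132) and miR-1a-3p at log2 -3.91 (SE 1.00), and 4 of 10 mesenchymal and muscle miRNAs passed (7 adjusted over the list alone). miR-1298-5p was 18.1-fold higher in fluid (log2 4.18, SE 0.77, edgeR adjusted p = 0.0011), miR-1264-5p had 15 counts in fluid and 0 in brushings, at least 3.28-fold higher, and miR-202-5p had 63 counts against 3. None of the 14 epithelial miRNAs was called by edgeR, none adjusted over the list alone, with values from log2 -0.63 for miR-375-3p to 0.22 for miR-183-5p. The brushings had 3 non-allergic libraries, and the count was 18 without immunized brushing library 1 and 17 without library 2. miR-133a-3p and miR-1a-3p were not called without library 1, miR-1264-5p without library 1 or 2, and miR-202-5p after 9 of the 24 single-library removals.

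Several miRNAs of the hematopoietic list were higher in lavage fluid of allergic than of non-allergic mice, relative to the other miRNAs. Non-allergic mice were untreated in set 2 and immunized in sets 3 and 4. The log2 difference in the hematopoietic share of the counts was 1.82 in set 2 and 0.82 and 1.11 in sets 3 and 4. miR-147-3p, which is induced in activated macrophages, rose 16.7-fold (log2 4.06, SE 0.65, edgeR adjusted p = 0.00101), from 13.9 ± 15.9 CPM in 7 non-allergic to 220 ± 121 CPM in 7 allergic libraries. miR-223-3p rose 8.34-fold (log2 3.06, SE 0.58, edgeR adjusted p = 0.00219), from 1032 ± 572 to 8307 ± 5901 CPM. miR-142a-3p, present in all blood cell lineages, rose 4.99-fold (log2 2.32, SE 0.33, edgeR adjusted p = 7.81e-04), from 1375 ± 426 to 7662 ± 4723 CPM. The largest decreases were in miR-195a-5p, which fell 4.25-fold (log2 -2.09, SE 0.35, edgeR adjusted p = 0.00112), from 1445 ± 989 to 322 ± 117 CPM, and its cluster partner miR-497a-5p (log2 -2.05, SE 0.36, edgeR adjusted p = 0.0014). Of 253 miRNAs tested in fluid, 84 passed, 48 higher and 36 lower.

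The other named increases in fluid included miR-130b-3p (7.28-fold, log2 2.86, SE 0.45), miR-338-3p (5.95-fold, log2 2.57, SE 0.44) and miR-340-5p (5.18-fold, log2 2.37, SE 0.33). They also included miR-142a-5p (4.91-fold, log2 2.30, SE 0.34), miR-486a/b-5p (4.81-fold, log2 2.27, SE 0.77), miR-144-3p (4.34-fold, log2 2.12, SE 0.77) and miR-15b-3p (4.27-fold, log2 2.09, SE 0.34). The other named decreases included the liver miRNA miR-122-5p (log2 -1.83, SE 0.46), miR-351-5p (log2 -1.73, SE 0.59), miR-199b-5p (log2 -1.65, SE 0.42) and miR-100-5p (log2 -1.64, SE 0.34). The last were miR-193a-3p (log2 -1.37, SE 0.35), the endothelial miR-126a-5p (log2 -1.34, SE 0.37), miR-503-5p (log2 -1.28, SE 0.47) and miR-214-3p (log2 -1.27, SE 0.29). Of these, miR-351-5p and miR-503-5p belong to a chromosome X cluster treated below. Its median in allergic fluid was log2 -3.35 against untreated mice but -0.303 against immunized mice, where no member was called. Within the library sets 2, 3 and 4 the log2 difference was 4.80, 1.49 and 3.82 for miR-147-3p, 4.33, 1.44 and 1.99 for miR-223-3p and -2.17, -1.64 and -1.94 for miR-195a-5p. Among those named, Mir147 lies at 122640803 to 122640881 of chromosome 2 in an exon of AA467197 and Mir223 at 96242817 to 96242926 of chromosome X. Mir142 lies at 87756864 to 87756927 of chromosome 11 in an intron of Mir142hg, Mir338 in an intron of Aatk and Mir340 in an intron of Rnf130, in mm10 coordinates. miR-195a-5p and miR-497a-5p come from neighbouring genes on chromosome 11, Mir497 at 70234717 to 70234800 and Mir195a at 70235042 to 70235135. Under total count scaling 34 were higher and 68 lower in fluid, and the median of all tested miRNAs moved from log2 0.006 to -0.207. The call of miR-486a/b-5p was lost without any of untreated libraries 1, 2 and 3, immunized 3 and 4 or allergic 2 and 6 (edgeR adjusted p 0.06 to 0.112). That of miR-144-3p was lost without any of untreated 1, 2 and 3, immunized 2, 3 and 4 or allergic 2, 5 and 6 (0.0637 to 0.146), that of miR-351-5p without untreated 1, 2 or 3, immunized 1 or allergic 1, 2, 3 or 6 (0.0515 to 0.113) and that of miR-503-5p without untreated 1, 2 or 3, immunized 1 or 4 or allergic 1, 2, 3, 4 or 7 (0.0582 to 0.138).

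By cell type, 7 of the 10 measured hematopoietic miRNAs rose in allergic fluid and none fell, also adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.468 with an estimated correlation). Beside miR-147-3p, miR-223-3p and both miR-142a strands these were miR-150-5p of mature lymphocytes (log2 1.51), miR-155-5p (log2 1.40) and miR-146a-5p (log2 1.40), while miR-342-3p (log2 -0.03), miR-181a-5p (log2 -0.15) and miR-181b-5p (log2 -0.16) did not pass. None of the 14 measured epithelial miRNAs was called by edgeR, none adjusted over the list alone (median log2 0.05, mean log2 -0.01; camera adjusted p = 0.853), with miR-200c-3p at log2 0.07, miR-205-5p at 0.05 and miR-182-5p at -0.50. With DESeq2 size factors, or with total count scaling, 1 epithelial miRNA was lower. Of 6 multiciliated miRNAs, miR-449c-5p (log2 1.67) and miR-449a-5p (log2 0.99) rose and the 4 of the miR-34b/c genes did not pass, with miR-34c-5p at log2 0.19 (camera adjusted p = 0.101). All 3 measured erythroid entries rose (miR-451a log2 2.08; camera adjusted p = 0.113) and both endothelial miR-126a strands fell (camera adjusted p = 0.101). Of the mesenchymal and muscle miRNAs 5 of 9 fell, among them miR-143-3p (log2 -0.92) and miR-145a-5p (log2 -0.99; camera adjusted p = 0.00363, adjusted p = 0.468 with an estimated correlation). In the liver list miR-122-5p and miR-192-5p (log2 -0.59) of 3 fell (camera adjusted p = 0.134). The counts of these last 5 lists were the same adjusted over the list alone. The call of miR-451a was lost without any of untreated libraries 1, 2 and 3, immunized 2, 3 and 4 and allergic 2, 4, 5 and 6 (edgeR adjusted p 0.0506 to 0.167), and under total count scaling 1 of the 3 erythroid entries was called. That of miR-126a-3p was lost without immunized library 1 or allergic library 2 (0.0565 to 0.0597), that of miR-145a-5p without immunized library 1 or 4 or allergic library 1 (0.0581 to 0.0664) and that of miR-192-5p without untreated 2, immunized 1 or allergic 1 or 2 (0.0535 to 0.0689).

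Among the activation and family lists, all 10 measured members of the miR-17-92 family, associated with proliferating cells, rose in allergic fluid, also adjusted over the list alone (camera adjusted p = 8.25e-04; adjusted p = 0.468 with an estimated correlation). The largest of these changes were in miR-25-3p (log2 1.85), miR-92a-3p (log2 1.49) and miR-18a-5p (log2 1.11). Of 10 activation-induced miRNAs 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0109, adjusted p = 0.468 with an estimated correlation). miR-21a-3p (log2 1.24) and miR-21a-5p (log2 0.76) rose beside miR-147-3p, miR-155-5p and miR-146a-5p, which are also on the hematopoietic list, and miR-31-5p fell (log2 -0.72). In the let-7 family 3 of 9 fell (the same adjusted over the list alone; let-7e-5p log2 -0.56; camera adjusted p = 0.0261, adjusted p = 0.473 with an estimated correlation). In the miR-30 family 2 of 5 fell (the same adjusted over the list alone; miR-30b-5p log2 -0.69; camera adjusted p = 0.134) and in the miR-23-27-24 clusters 2 of 7 fell (1 adjusted over the list alone; camera adjusted p = 0.152). With DESeq2 size factors 8 of the miR-17-92 members were higher. Under total count scaling 4 of the miR-17-92 members were higher, and 8 let-7, 4 miR-30 and 4 miR-23-27-24 members lower, with no member called in the opposite direction. Calls of single small changes rested on single libraries, since miR-19a-3p was not called after 12 of the 14 single-library removals, miR-19b-3p after 11, miR-31-5p after 10, miR-20a-5p after 9, miR-17-3p after 7 and miR-30b-5p after 3. The same held for miR-24-1-5p after 11, let-7a-5p after 5, let-7d-5p, miR-24-3p and miR-106b-5p after 2 each and miR-93-5p after 1. Without allergic library 1 or 2, these 2 let-7 and 2 miR-24 calls were all lost. Without untreated library 2 or allergic library 6, miR-17-3p, miR-19a-3p, miR-19b-3p, miR-20a-5p and miR-106b-5p all lost their call.

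In lavage cells of allergic mice, miR-150-5p of mature lymphocytes was among the largest increases, and most epithelial miRNAs fell. miR-150-5p rose 12.1-fold (log2 3.59, SE 0.30, edgeR adjusted p = 3.99e-07), from 1861 ± 737 CPM in 7 non-allergic to 23000 ± 8041 CPM in 7 allergic libraries. miR-155-5p, which is induced in activated lymphocytes and macrophages, rose 5.39-fold (log2 2.43, SE 0.37, edgeR adjusted p = 9.57e-05), and miR-147-3p rose 10.5-fold (log2 3.39, SE 0.49, edgeR adjusted p = 6.67e-05), from 39.5 ± 32.8 to 477 ± 221 CPM. The basal epithelial miRNA miR-205-5p fell 5.36-fold (log2 -2.42, SE 0.24, edgeR adjusted p = 2.27e-06), from 2417 ± 956 to 449 ± 128 CPM, and the multiciliated miR-34c-5p fell 4.07-fold (log2 -2.03, SE 0.32, edgeR adjusted p = 1.30e-04). Of 217 miRNAs tested in the cells, 122 passed, 64 higher and 58 lower.

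Among the largest increases in cells were miR-20b-5p, a paralog of miR-20a-5p, with 8 counts in 7 non-allergic and 332 in 7 allergic libraries, and miR-139-5p (11.3-fold, log2 3.50, SE 0.59). Also named as increased were miR-149-5p (8.26-fold, log2 3.05, SE 0.54), miR-340-5p (6.31-fold, log2 2.66, SE 0.37), miR-669a/o-3p (5.51-fold, log2 2.46, SE 0.39), miR-142a-3p (5.16-fold, log2 2.37, SE 0.20) and miR-467a/b-5p (4.66-fold, log2 2.22, SE 0.60). The smooth muscle miRNA miR-145a-5p fell (log2 -3.07, SE 0.97, edgeR adjusted p = 0.0173; -3.21, -0.05 and -3.77 within sets 2, 3 and 4), but its call was lost without allergic library 6 (edgeR adjusted p = 0.052) and without the filter on low counts (edgeR adjusted p = 0.0828). It was at 4460 CPM in immunized library 4 and 260.1 CPM in the next immunized library, and without library 4 the difference was log2 -1.852. The other named decreases were miR-551b-3p (log2 -2.50, SE 0.63), miR-764-5p (log2 -2.37, SE 0.42) and miR-199a/b-3p (log2 -2.06, SE 0.37). They also included miR-125a-5p (log2 -2.01, SE 0.28), miR-34b-5p (log2 -1.99, SE 0.35), miR-375-3p (log2 -1.96, SE 0.28) and miR-125b-5p (log2 -1.96, SE 0.22). Within the library sets 2, 3 and 4 the log2 difference was 3.75, 3.36 and 3.96 for miR-150-5p and -2.22, -2.25 and -2.62 for miR-205-5p. Mir150 lies at 45121757 to 45121821 of chromosome 7, Mir205 at 193507463 to 193507530 of chromosome 1 in an exon of 4631405K08Rik, and Mir20b at 52742113 to 52742192 of chromosome X. Under total count scaling 34 were higher and 67 lower in cells, and the median of all tested miRNAs moved from log2 0.04 to -0.317. The median total was 145613 counts in non-allergic and 222614 in allergic cell libraries.

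By cell type, 8 of 12 hematopoietic miRNAs rose in allergic lavage cells and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.468 with an estimated correlation). miR-223-3p (log2 2.01) and miR-223-5p (log2 2.07) were among those that rose, and miR-511-3p of Mrc1 (log2 -1.52), miR-342-3p (log2 -0.85) and miR-181b-5p (log2 -0.70) fell. Of 11 epithelial miRNAs 10 fell, among them miR-141-3p (log2 -1.56) and miR-200b-3p (log2 -1.46), and the keratinocyte miRNA miR-203-3p rose (log2 1.29), also adjusted over the list alone (camera adjusted p = 8.25e-04; adjusted p = 0.468 with an estimated correlation). In the multiciliated list 5 of 6 fell (the same adjusted over the list alone; miR-449a-5p log2 -1.28; camera adjusted p = 0.0121, adjusted p = 0.468 with an estimated correlation), and miR-449c-5p did not pass (log2 -0.29). None of the 5 erythroid entries was called by edgeR or adjusted over the list alone (miR-451a log2 0.56; median log2 0.36 with camera's direction down, adjusted p = 0.972). In the mesenchymal and muscle list 2 of 3 fell (3 adjusted over the list alone; camera adjusted p = 0.106). In the liver list miR-192-5p of 2 rose (log2 0.58; none adjusted over the list alone; camera adjusted p = 0.415), but its call was lost in 9 of the 14 single-library removals (edgeR adjusted p 0.0562 to 0.0952). Of the endothelial miRNAs only miR-126a-3p was tested, and it did not pass (log2 -1.10, SE 0.61, edgeR adjusted p = 0.134). Under total count scaling the hematopoietic counts were 7 and 3, the epithelial 1 and 10 and the multiciliated 0 and 5, while the erythroid median turned to log2 -0.126.

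All but miR-106b-5p (log2 0.52) of the 11 measured miR-17-92 members rose in allergic cells, 10 in all (11 adjusted over the list alone; camera adjusted p = 8.25e-04, adjusted p = 0.468 with an estimated correlation), among them miR-92a-3p (log2 1.73) and miR-18a-5p (log2 1.33). Of 10 activation-induced miRNAs 7 rose (the same adjusted over the list alone), with miR-132-3p at log2 1.08 and miR-221-3p at 1.03, and miR-21a-5p (log2 -0.23) and miR-31-5p (log2 -0.19) did not pass (camera adjusted p = 0.0524). In the let-7 family 4 of 9 fell, with let-7e-5p at log2 -1.89 (camera adjusted p = 0.201), and in the miR-23-27-24 clusters 2 of 6 fell (camera adjusted p = 0.271). In the miR-30 family 2 of 5 fell and miR-30e-5p rose (log2 0.54; camera adjusted p = 0.54). These 3 counts were the same adjusted over the list alone. Some of these calls rested on single libraries, since miR-30b-5p was not called after 13 of the 14 single-library removals (edgeR adjusted p 0.0551 to 0.148), let-7a-5p after 11 (0.0551 to 0.163) and let-7f-5p after 4 (0.0519 to 0.0703). Of the miR-17-92 members, miR-93-5p was not called after 5 removals and miR-25-3p after 3. The call of miR-132-3p was lost in 7 of the 14 single-library removals, without untreated 2 or 3, immunized 3 or 4 or allergic 2, 6 or 7 (edgeR adjusted p 0.052 to 0.078), and under total count scaling 3 activation-induced miRNAs were higher.

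**Figure D1:**
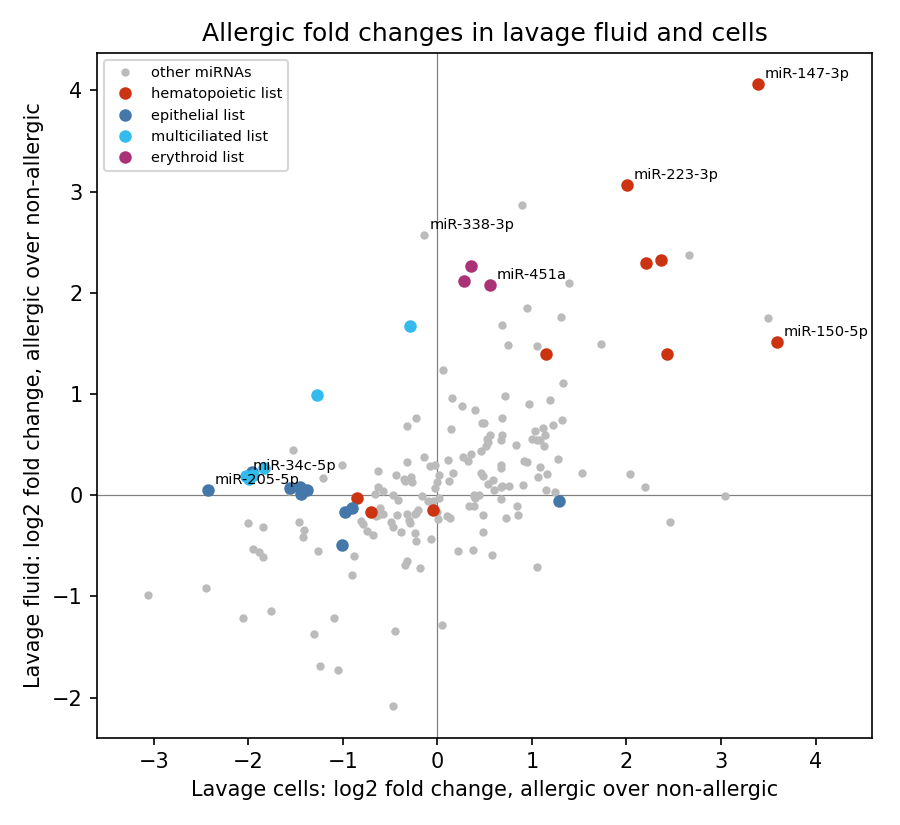
Each point is 1 of 196 miRNAs tested in both lavage fluid and lavage cells, placed by its log2 fold change of allergic over non-allergic libraries in cells (x axis) and in fluid (y axis), with colours for the hematopoietic, epithelial, multiciliated and erythroid lists. Of the epithelial miRNAs 10 lie below 0 in cells (miR-205-5p at log2 0.05 in fluid and -2.42 in cells) and miR-203-3p lies above 0 (log2 1.29 in cells), while miR-147-3p is above 3 on both axes.

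Whether fluid and cells changed alike was tested as the difference between their allergic changes. Epithelial and multiciliated miRNAs differed as groups by camera. Relative to cells, the change in fluid was higher for 11 of 14 and lower for miR-203-3p (12 and 1 adjusted over the list alone; camera adjusted p = 2.19e-04, adjusted p = 0.503 with an estimated correlation). It was higher for all 6 multiciliated miRNAs, also adjusted over the list alone (camera adjusted p = 2.19e-04; adjusted p = 0.319 with an estimated correlation). miR-205-5p differed by log2 2.64 (SE 0.38, edgeR adjusted p = 2.31e-05) and miR-338-3p by 2.84 (SE 0.50, edgeR adjusted p = 1.32e-04). miR-511-3p differed by 3.25 (SE 0.87, edgeR adjusted p = 0.00674), miR-3102-3p by 3.23 (SE 0.60) and miR-764-5p by 2.83 (SE 1.04, edgeR adjusted p = 0.0481). In the other direction miR-149-5p differed by log2 -2.91 (SE 0.62, edgeR adjusted p = 8.92e-04), miR-669a/o-3p by -2.57 (SE 0.53), miR-5100 by -2.32 (SE 0.58), miR-150-5p by -1.95 (SE 0.44) and miR-181c-5p by -1.91 (SE 0.39). Of the 13 hematopoietic miRNAs, 2 differed upward (miR-511-3p and miR-342-3p) and 1 downward (miR-150-5p; 3 and 1 adjusted over the list alone; camera adjusted p = 0.888). In all, 68 of 276 miRNAs differed, 54 higher and 14 lower in fluid, with a median of log2 0.358 over all tested, so that these counts are relative to a shifted centre. miR-764-5p was not called after 21 of the 28 single-library removals (edgeR adjusted p 0.0566 to 0.132) and miR-342-3p after 15 (0.0527 to 0.269). Of the epithelial miRNAs, miR-183-5p was not called after 19, miR-141-5p after 17, miR-200a-5p after 15 and miR-200b-5p after 7. Across the 196 miRNAs tested in both, the 2 sets of fold changes had a Pearson r of 0.564. They are from separate libraries, but fluid and cells may come from the same mice, so they may not be independent. miRNAs are not independent replicates. Of 46 miRNAs called in both, 28 were higher in both, against 13.4 for independent lists of these sizes, and 16 lower in both, against 6.63.

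In serum, no miRNA passed between allergic and non-allergic mice. The lowest p values were those of miR-708-5p (log2 -1.61, SE 0.46), miR-10a-3p (log2 1.32, SE 0.39) and miR-122-5p (log2 -1.11, SE 0.35), each at an edgeR adjusted p of 0.372. Of 347 miRNAs tested by edgeR 0 passed, 27 had an unadjusted p under 0.05, and DESeq2 called 0. miR-223-3p was at 14140 ± 8037 CPM in 7 allergic and 10522 ± 6761 CPM in 7 non-allergic serum libraries (log2 0.53), and miR-147-3p at 75.8 ± 37.3 against 49.9 ± 37.9 CPM (log2 0.77). No list member passed; adjusted over the list alone, 2 of 4 liver miRNAs were lower, miR-122-5p and miR-122-3p, and 1 of 11 activation-induced, miR-31-5p (log2 -1.08). None of the other 10 lists had a call. By camera the activation-induced list (adjusted p = 0.0109; adjusted p = 0.468 with an estimated correlation) and the hematopoietic list (adjusted p = 0.038; adjusted p = 0.468 with an estimated correlation) were shifted up, with medians of log2 0.37. The let-7 family was shifted down (median log2 -0.31; adjusted p = 0.0243; adjusted p = 0.51 with an estimated correlation).

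The allergic change in fluid was tested against that in serum. Among the largest differences were miR-147-3p at log2 3.26 (SE 0.77, edgeR adjusted p = 0.00603), miR-486a/b-5p at 2.86 (SE 0.80) and miR-338-3p at 2.73 (SE 0.55), all higher in fluid. So were miR-130b-3p at 2.696 (SE 0.43, edgeR adjusted p = 2.26e-04) and miR-223-3p at 2.37 (SE 0.59, edgeR adjusted p = 0.009). miR-497a-5p (log2 -2.13, SE 0.43) and miR-195a-5p (log2 -1.83, SE 0.45) were lower. In all 26 of 340 miRNAs passed, 24 higher and these 2 lower. Of 12 hematopoietic miRNAs 6 were higher in fluid (8 adjusted over the list alone; camera adjusted p = 6.78e-04, adjusted p = 0.273 with an estimated correlation). The same held for 1 of 5 erythroid entries (5 adjusted over the list alone) and 3 of 12 miR-17-92 members (5 adjusted over the list alone). The call of miR-486a/b-5p, the erythroid one, was lost in 10 of the 28 single-library removals (edgeR adjusted p 0.0571 to 0.0839). These were fluid immunized 4 and allergic 2, and serum untreated 1 and 2, immunized 1 and 3 and allergic 2, 3, 4 and 6. The count was 17 without untreated serum library 2.

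In the epithelial brushings of allergic mice, red blood cell miRNAs rose most. miR-144-5p rose 28.9-fold (log2 4.85, SE 0.42, edgeR adjusted p = 0.00566) and miR-144-3p 15.8-fold (log2 3.99, SE 0.43, edgeR adjusted p = 0.00987). miR-451a rose 11.3-fold (log2 3.50, SE 0.55, edgeR adjusted p = 0.0365) and miR-486a/b-5p 8.32-fold (log2 3.06, SE 0.51, edgeR adjusted p = 0.0365). miR-147-3p rose 7.96-fold (log2 2.99, SE 0.46, edgeR adjusted p = 0.0365), from 15.3 ± 9.16 CPM in 3 non-allergic to 121 ± 50.9 CPM in 3 allergic libraries. miR-21a-3p (log2 1.44, SE 0.26), miR-142a-3p (log2 1.41, SE 0.23) and miR-142a-5p (log2 1.38, SE 0.23) rose as well, and miR-145a-5p fell (log2 -1.25, SE 0.17, edgeR adjusted p = 0.0301). These are all 9 of the 306 tested miRNAs that passed. None of them was called without the term for the set or with the replicate block, and 0 miRNAs passed in brushings of sets 3 and 4 alone, a fit added after seeing the data.

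The erythroid share of the counts was higher in allergic brushings in each library set (log2 4.54, 2.15 and 3.51 within sets 2, 3 and 4; exact permutation p = 0.25, the smallest possible). miR-451a took 15.5% of the counts of allergic brushing library 1, whose mean Spearman correlation with the other brushings was 0.903, against at least 0.951 for the other 5. All 4 erythroid entries rose, also adjusted over the list alone (camera adjusted p = 7.24e-06; adjusted p = 0.468 with an estimated correlation). So did 3 of 10 hematopoietic (the same adjusted over the list alone; camera adjusted p = 8.25e-04, adjusted p = 0.468 with an estimated correlation). Of 10 activation-induced miRNAs 2 rose (the same adjusted over the list alone; camera adjusted p = 0.0171, adjusted p = 0.468 with an estimated correlation). Of 10 mesenchymal and muscle miRNAs 1 fell (3 adjusted over the list alone; camera adjusted p = 1.19e-04, adjusted p = 0.468 with an estimated correlation). No miRNA of the miR-17-92 family (camera adjusted p = 0.00264; adjusted p = 0.468 with an estimated correlation), or of the epithelial, multiciliated, endothelial, liver, miR-23-27-24, let-7 and miR-30 lists passed. Adjusted over the list alone only miR-449c-5p of the multiciliated list did (log2 1.28). These 7 lists had camera adjusted p values of 0.835, 0.345, 0.152, 0.415, 0.125, 0.761 and 0.345, in that order. The comparison had 2 residual degrees of freedom: 0 miRNAs passed without immunized brushing library 2, 4 without immunized library 1 or allergic library 2, 19 without allergic library 1 and 27 without untreated library 1. The call of miR-451a was also lost without allergic library 3, and no erythroid call was lost without allergic library 1. Allergic library 1 and untreated library 1 are the only brushings of set 2. Without either of them the comparison rests on sets 3 and 4, as in the fit of those sets alone, where 0 passed. The 19 and 27 calls and the kept erythroid calls therefore do not show that the result holds without set 2. Total count scaling gave 5 higher and 1 lower, with a shift of the median of all from log2 -0.06 to -0.148. When the allergic changes in fluid and brushings were tested against each other, edgeR called 0 of 316 miRNAs, with 28 at an unadjusted p under 0.05 and 1 called by DESeq2. The lowest p values were those of miR-338-3p (log2 2.95, SE 0.70), miR-340-5p (log2 2.05, SE 0.54) and miR-497a-3p (log2 -3.85, SE 1.09), at edgeR adjusted p values of 0.206 to 0.292. There 2 were called without allergic fluid library 7.

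Against untreated mice alone, miR-147-3p and miR-223-3p rose in allergic fluid and a group of chromosome X miRNAs fell. miR-147-3p (edgeR adjusted p = 6.29e-04) had 4 counts in 3 untreated and 155 in the 3 allergic libraries of the same set, too few in untreated mice for an exact fold. miR-223-3p rose 22.5-fold (log2 4.49, SE 0.70, edgeR adjusted p = 8.42e-04), from 497 ± 148 to 10900 ± 5480 CPM. miR-449a-3p (log2 3.66, SE 0.84), miR-144-5p (log2 3.47, SE 1.13, edgeR adjusted p = 0.0359) and miR-142a-5p (log2 3.11, SE 0.43) rose. miR-322-3p fell 17.5-fold (log2 -4.13, SE 0.58, edgeR adjusted p = 4.95e-04), from 818 ± 287 to 44.7 ± 20.4 CPM in the same libraries. The allergic libraries of sets 3 and 4 had 135 ± 16.2 and 272 ± 129 CPM (n = 2 each), and over all allergic libraries without the set term the log2 difference was -2.524. miR-351-5p (log2 -3.76, SE 0.54), miR-542-3p (log2 -3.43, SE 0.71), miR-450a-5p (log2 -3.26, SE 0.57) and miR-503-5p (log2 -2.703, SE 0.54) fell. Of 294 miRNAs 83 passed, 48 higher and 35 lower (35 and 64 with total count scaling, whose median of all moved from log2 0.07 to -0.261). The count was 50 without untreated library 2, and miR-144-5p was lost without untreated library 1, 2 or 3 (edgeR adjusted p 0.0685 to 0.111) and without the term for the set (edgeR adjusted p = 0.0902). Against immunized mice, the allergic fluid had 16 calls, 13 higher and 3 lower (14 and 10 with total count scaling, median of all from log2 -0.04 to -0.181). miR-147-3p (log2 3.02, SE 0.68, edgeR adjusted p = 0.0345), miR-130b-3p (log2 2.79, SE 0.59), miR-338-3p (log2 2.31, SE 0.58), miR-340-5p (log2 2.21, SE 0.44) and miR-15b-3p (log2 1.91, SE 0.44) were among those that rose. Those that fell were miR-195a-5p (log2 -1.88, SE 0.46), miR-497a-5p (log2 -1.79, SE 0.47) and miR-34a-5p (log2 -0.83, SE 0.23). That count was 0 without immunized library 2, 3 or 4 or allergic library 1, 4 or 6, 5 without allergic library 2, 25 without untreated library 3 and 29 without untreated library 1, so each of these calls rests on single libraries. The change against untreated mice comes from set 2 and that against immunized mice from sets 3 and 4. Across 294 miRNAs they had a Pearson r of 0.671 and a Spearman rho of 0.604. Of 14 miRNAs called in both, 12 were higher in both, against 2.12 for independent lists, and 2 lower in both, against 0.357.

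In lavage cells the allergic change was found against both kinds of non-allergic mice. Against untreated mice miR-139-5p rose 34-fold (log2 5.09, SE 0.71) and miR-340-3p 14.5-fold (log2 3.86, SE 0.56). miR-149-5p (edgeR adjusted p = 3.65e-05), miR-147-3p and miR-20b-5p rose too, with 607, 784 and 236 counts in the 3 allergic and 5, 7 and 5 in the 3 untreated libraries of set 2. miR-448-3p (log2 -2.82, SE 0.79), miR-296-5p (log2 -2.65, SE 0.67), miR-450b-3p (log2 -2.61, SE 0.69) and miR-34c-5p (log2 -2.55, SE 0.46) fell. Without the term for the set miR-448-3p, miR-296-5p and miR-450b-3p were not called (log2 -1.349, -1.093 and -1.091), and the call of miR-448-3p was lost without untreated library 1 (edgeR adjusted p = 0.0777). miR-551b-3p had 2 counts in the 3 allergic and 58 in the 3 untreated libraries of set 2. Of 258 miRNAs 102 passed, 55 higher and 47 lower (30 and 44 with total count scaling, median of all from log2 0.145 to -0.15). Against immunized mice miR-150-5p rose 13.5-fold (log2 3.76, SE 0.39, edgeR adjusted p = 1.13e-05), miR-669a/o-3p 7.67-fold (log2 2.94, SE 0.48) and miR-147-3p 6.45-fold (log2 2.69, SE 0.52). miR-764-5p (log2 -2.51, SE 0.55), miR-205-5p (log2 -2.40, SE 0.33), miR-1264-5p (log2 -1.81, SE 0.53), miR-375-3p (log2 -1.80, SE 0.39) and miR-125a-5p (log2 -1.69, SE 0.37) fell. miR-106a-5p had 55 counts in 4 allergic and 1 in 4 immunized libraries, and its neighbour miR-20b-5p 96 and 3. In that comparison 0 passed with the replicate block, which leaves fewer degrees of freedom. In the main fit 99 passed, 57 higher and 42 lower (23 and 56 with total count scaling, median of all from log2 -0.04 to -0.586). All 12 miR-17-92 members rose, also adjusted over the list alone (camera adjusted p = 5.51e-06; adjusted p = 0.345 with an estimated correlation). Across the 258 miRNAs the changes of set 2 and of sets 3 and 4 had a Pearson r of 0.781 and a Spearman rho of 0.776. Of these 69 were called in both, 35 higher in both, against 12.2 for independent lists, and 33 lower in both, against 7.65.

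Some miRNAs passed between allergic and untreated serum, compared within set 2, while none passed between allergic and immunized serum, compared within sets 3 and 4. Against untreated mice, allergic serum had more miR-34a-5p, a target of p53 (6.48-fold, log2 2.697, SE 0.53, edgeR adjusted p = 0.00263). It was at 68.9 ± 55.7 CPM in 3 untreated and 452 ± 64.3 CPM in the 3 allergic libraries of the same set, and at 397 ± 161 CPM in 4 immunized libraries. miR-188-5p (log2 2.07, SE 0.44), miR-342-3p (log2 1.93, SE 0.44), miR-29b-3p (log2 1.92, SE 0.37) and miR-362-3p (log2 1.78, SE 0.44) rose too. miR-455-3p (log2 -3.97, SE 0.65, edgeR adjusted p = 0.00115), miR-202-5p (log2 -3.74, SE 0.64), miR-322-3p (log2 -2.87, SE 0.42, edgeR adjusted p = 5.06e-04), miR-296-5p (log2 -2.82, SE 0.51) and miR-351-5p (log2 -2.38, SE 0.44) fell. Without the term for the set miR-202-5p turned to log2 0.973, and miR-322-3p (log2 -0.848) and miR-351-5p (log2 -0.845) were not called. Of 409 miRNAs 38 passed, 16 higher and 22 lower (0 and 20 with total count scaling, median of all from log2 0.03 to -0.412). The count was 25 without untreated library 3, 21 without allergic library 1, 17 without allergic library 2 and 19 without allergic library 3. Depth did not overlap between these groups. The 3 untreated serum libraries had totals of 137638 to 890460 counts and the 3 allergic ones of the same set 1193226 to 2143704. An effect of depth was not tested for this comparison. Between allergic and immunized serum edgeR called 0, with 7 at an unadjusted p under 0.05 and 0 called by DESeq2. Total count scaling also called 0 and moved the median of all from log2 -0.01 to 0.204. The lowest p values there were those of miR-708-5p (log2 -1.996, SE 0.62), miR-202-3p (log2 1.28, SE 0.43) and miR-28a-5p (log2 -1.26, SE 0.44), at an edgeR adjusted p of 0.997. In simulated data with a fixed dispersion of 0.15 this comparison found 30.8% of 2-fold and 93.3% of 4-fold changes. That spread was not fitted to serum, so the power in the real libraries is not known.

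Immunized and untreated libraries were never in the same set, so their comparison runs through the allergic libraries of both. In serum 13 of 409 miRNAs passed between them, 3 higher and 10 lower (0 and 8 with total count scaling, median of all from log2 0.08 to -0.572). miR-34a-5p (log2 2.69, SE 0.67), miR-342-3p (log2 2.06, SE 0.56) and miR-29b-3p (log2 1.94, SE 0.48) were higher. miR-202-5p (log2 -4.64, SE 0.80), miR-455-3p (log2 -3.84, SE 0.79), miR-322-3p (log2 -3.48, SE 0.53, edgeR adjusted p = 9.50e-04), miR-351-5p (log2 -2.89, SE 0.55) and miR-296-5p (log2 -2.59, SE 0.64) were among those lower. Without the term for the set, miR-202-5p turned to log2 0.999, and miR-322-3p, miR-351-5p, miR-296-5p and miR-455-3p were not called (log2 -0.796, -0.729, -1.204 and -1.729). miR-342-3p was not called after 9 of the 14 single-library removals, miR-296-5p after 7, miR-29b-3p after 6 and miR-34a-5p after 3. The serum count was 22 without untreated library 2, 21 without immunized library 3, 8 without immunized library 2 or allergic library 2, 3 or 4, and 7 without allergic library 5. In fluid the 3 calls were miR-322-3p (log2 -3.92, SE 0.71, edgeR adjusted p = 0.0253), miR-351-5p (log2 -3.28, SE 0.66, edgeR adjusted p = 0.0358) and miR-450a-5p (log2 -3.28, SE 0.72, edgeR adjusted p = 0.0491), all lower in immunized mice. Without the term for the set none of these 3 was called (log2 -1.836, -1.056 and -2.01). The count was 15 without untreated library 1, 7 without immunized library 1, 6 without allergic library 6, 1 without allergic library 5 and 0 without untreated 2 or 3, immunized 3 or 4 or allergic 1, 2 or 3. In cells the 2 calls were miR-551b-3p (log2 -4.97, SE 0.85, edgeR adjusted p = 0.00826) and miR-296-5p (log2 -4.22, SE 0.88, edgeR adjusted p = 0.0308). miR-31-5p did not pass (log2 -2.32, SE 0.58, edgeR adjusted p = 0.0602), and total count scaling moved the median of all from log2 -0.02 to 0.204. Without the term for the set neither of the 2 was called (log2 -0.346 and -2.1) and miR-31-5p was (log2 -1.792). miR-551b-3p was at 163 ± 73.6 CPM in untreated and 138 ± 69.8 CPM in 4 immunized libraries, while the allergic libraries that link these groups had 2.34 ± 2.79 CPM in set 2 and 62.2 ± 22.8 and 53.6 ± 6.18 CPM in sets 3 and 4. The count was 9 without untreated library 1, 6 without immunized library 1, 4 without allergic library 7, 0 without allergic library 2 and 1 without untreated 2 or 3, immunized 2 or 3 or allergic 1, 3, 5 or 6.

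The genes of miR-322, miR-503, miR-351, miR-542 and miR-450 form a cluster on the minus strand of chromosome X, from Mir450b at 53047997 to 53048078 to Mir322 at 53054255 to 53054349. They were looked at as a group after their values had been seen. In fluid 9 of its 10 tested members were lower in allergic than untreated mice (median log2 -3.35) and 3 were lower in immunized than untreated mice (median log2 -3.28). These 2 comparisons share the untreated and allergic libraries, so the second is not a separate finding. In serum 5 of 11 tested members were lower in allergic than untreated mice (median log2 -1.68) and 3 in immunized (median log2 -2.15), and in cells 3 of 8 (median log2 -1.13) and 0 (median log2 -0.161). The medians of immunized against untreated mice depend on the allergic libraries that link the sets. Without that link they were log2 -1.48 in fluid and -0.231 in serum. Between allergic and immunized mice no member was called by edgeR, with medians of log2 -0.303 in fluid, 0.429 in serum and -0.526 in cells.

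**Figure D2:**
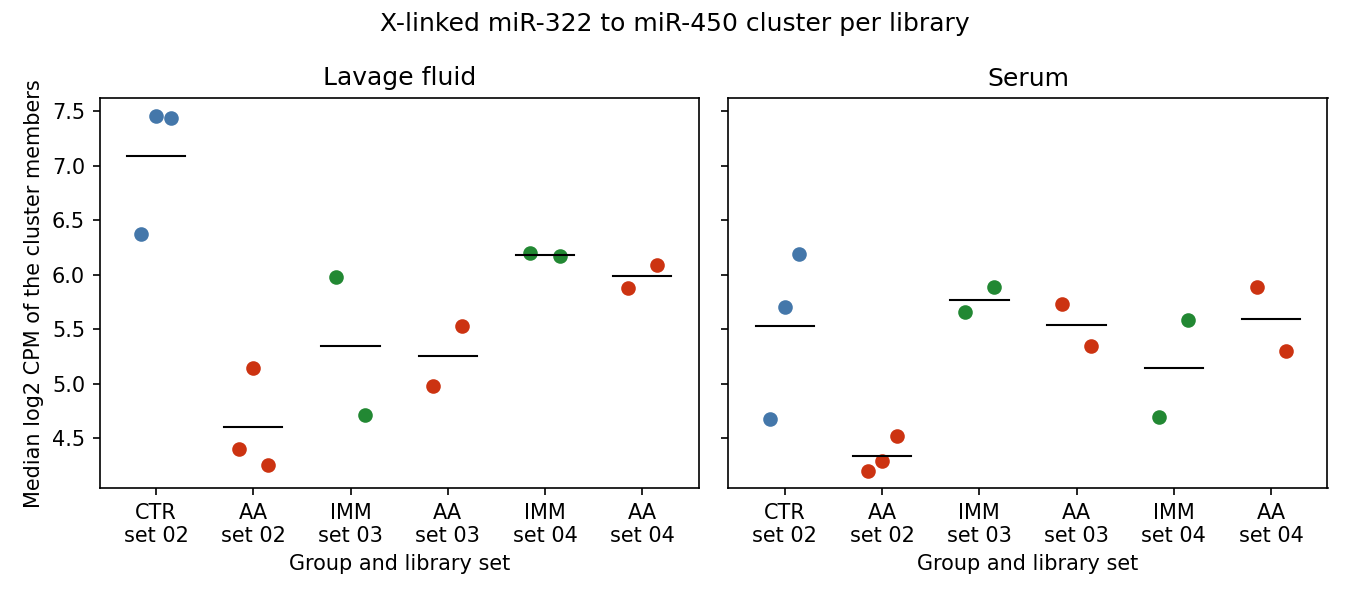
The median log2 CPM of the chromosome X cluster members is shown for each lavage fluid and serum library (dots) by group and library set, with black lines for the means of the libraries. Untreated fluid libraries lie between 6.37 and 7.46, above the allergic fluid libraries of the same set, between 4.25 and 5.15.

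The share of all miRNA counts taken by a list was compared with an exact 2-sided permutation test within library sets, with 720 permutations and 0.00278 as the smallest p possible. Hematopoietic miRNAs took 2.47% ± 1.06 of the counts in 7 allergic and 0.907% ± 0.132 in 7 non-allergic fluid libraries (log2 difference 1.33, exact permutation p = 0.00278, adjusted over 9 tests 0.00833; 1.82, 0.82 and 1.11 within sets 2, 3 and 4). In cells the hematopoietic share was 21.9% ± 9.14 against 6.86% ± 2.19 (log2 1.64, exact permutation p = 0.00278, adjusted 0.00833; 2.35, 1.01 and 1.21 within sets), and in serum 4.43% ± 2.81 against 3.79% ± 2.24 (log2 0.20, exact permutation p = 0.544, adjusted 0.7). Epithelial miRNAs took 13.7% ± 2.94 of the counts of allergic and 15.2% ± 2.97 of non-allergic fluid (log2 -0.15, exact permutation p = 0.353, adjusted 0.604; -0.07, -0.03 and -0.40 within sets). They took 0.741% ± 0.346 against 2.59% ± 0.844 in cells (log2 -1.90, exact permutation p = 0.00278, adjusted 0.00833; -1.83, -1.39 and -2.50 within sets). In serum they took 0.366% ± 0.22 against 0.367% ± 0.233 (exact permutation p = 0.992, adjusted 0.992). The erythroid share of fluid was 4.52% ± 5.46 in allergic and 1.07% ± 0.661 in non-allergic libraries (log2 1.61, exact permutation p = 0.0528, adjusted 0.119; 1.27, 1.09 and 2.63 within sets). Its unadjusted p passed without immunized library 1 (log2 1.93) or allergic library 3 (log2 1.83). The erythroid share was 22.1% ± 18 against 23.7% ± 18.2 in cells (exact permutation p = 0.786, adjusted 0.884) and 43.8% ± 17.9 against 47.8% ± 15 in serum (exact permutation p = 0.403, adjusted 0.604).

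**Figure D3:**
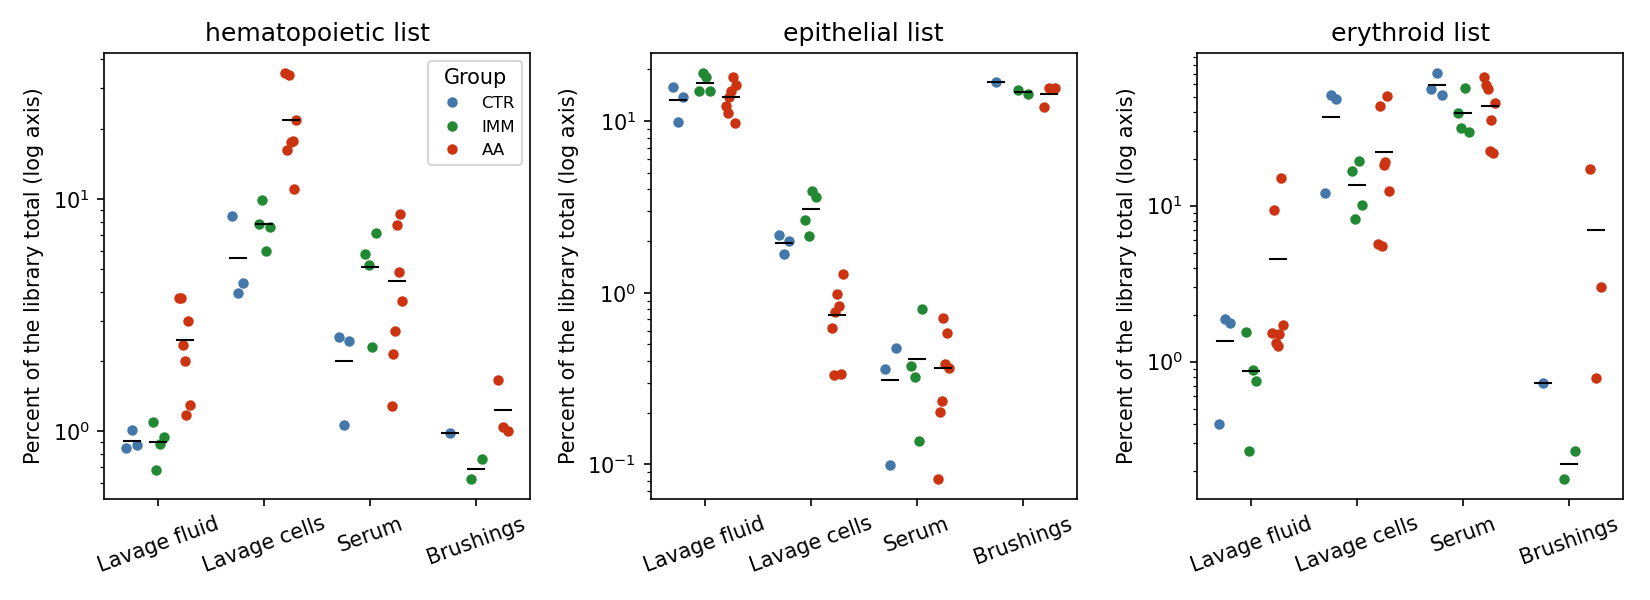
The percent of each library's miRNA counts taken by the hematopoietic, epithelial and erythroid lists is shown on a log axis for the 48 libraries (dots) by compartment and group, with black lines for group means. The hematopoietic share was 2.47% in allergic and 0.907% in non-allergic lavage fluid, and the epithelial share 0.741% in allergic and 2.59% in non-allergic lavage cells.

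The likeness of each fluid library to the mean profile of another compartment was measured as Spearman's rho over 452 miRNAs and tested by the same exact permutation. Allergic fluid was closer to lavage cells than non-allergic fluid. The rho was 0.838 ± 0.0176 in 7 allergic and 0.798 ± 0.0219 in 7 non-allergic libraries (difference 0.0397, exact permutation p = 0.00278, adjusted over 3 tests 0.00833; 0.0604, 0.0137 and 0.0345 within sets 2, 3 and 4). Its rho with brushings was 0.912 ± 0.0194 against 0.927 ± 0.00914 (difference -0.0156, exact permutation p = 0.111, adjusted 0.167). It passed unadjusted without allergic library 3 (difference -0.0198) or allergic library 5 (difference -0.0206). Its rho with serum was 0.736 ± 0.0193 against 0.727 ± 0.022 (difference 0.00895, exact permutation p = 0.436, adjusted 0.436).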

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

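Single libraries far from the rest of their group were looked for in 116 groups of 4 to 10 libraries with Dixon's test, which by chance marks about 1 in 20 groups, 5.8 here, and 14 were found. In allergic fluid, library 6 stood out by a likeness to serum of 0.7787 (next 0.7352), miR-486a/b-5p at 7219 CPM (next 2259) and miR-126a-5p at 745.5 CPM (next 343.7), library 3 by miR-199b-5p at 438 CPM (next 187.2), and library 4 by a low miR-193a-3p of 77.07 CPM (next 171). In immunized fluid, library 4 had a total of 561803 counts (next 308063) and library 1 had miR-142a-5p at 1243 CPM (next 782.6). In allergic lavage cells, library 2 had a total of 960796 counts (next 391440) and library 6 had miR-150-5p at 40179 CPM (next 22717). In immunized lavage cells, library 2 had miR-139-5p at 947.5 CPM (next 270.7) and miR-467a/b-5p at 143.3 CPM (next 13.77), library 4 had miR-145a-5p at 4460 CPM (next 260.1), and library 1 had miR-551b-3p at 242.4 CPM (next 111.5). In allergic serum, library 4 had miR-122-5p at 3003 CPM (next 1349).

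The allergic change differed between fluid and serum, by an interaction test, for 26 miRNAs. Fluid minus serum was log2 3.258 for miR-147-3p, 2.862 for miR-486a/b-5p, 2.729 for miR-338-3p, 2.696 for miR-130b-3p, 2.365 for miR-223-3p, -2.126 for miR-497a-5p and -1.826 for miR-195a-5p. It differed between fluid and lavage cells for 68 miRNAs. Fluid minus cells was log2 3.247 for miR-511-3p, 3.232 for miR-3102-3p, 2.844 for miR-338-3p, 2.827 for miR-764-5p, 2.642 for miR-205-5p, -2.913 for miR-149-5p, -2.575 for miR-669a/o-3p, -2.315 for miR-5100, -1.955 for miR-150-5p and -1.915 for miR-181c-5p.

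Of the tests below, those of red blood cell RNA, cells left in the fluid, epithelial cells per pellet and a single untreated library had their predictions written before the values of that test were computed but after the pattern was seen; those of depth, challenge (in fluid and serum, and in cells), library sets, other splits and the bound from other miRNAs only were chosen after the result was seen.

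Hematopoietic miRNAs that rose in allergic fluid could come with red blood cell RNA, from lavage cells broken or left in the fluid, or from release by living cells. With the miR-451a level as a covariate the median log2 change of the 7 miRNAs was 1.82, against 2.30 without it, and 7 of 7 were still called, which argues against RNA that follows miR-451a but leaves RNA of other blood cells open. The share of pellet RNA that the miRNAs would need was 3.48% to 23.5% of the fluid, and in 6 of 7 allergic libraries it lay more than 1.5 times above the bound of 1.92% to 6.59% set by the 10 miRNAs in highest excess in pellets. In libraries 2, 4, 5 and 7 that bound was set by a miRNA of the 7 themselves, and from the other 6 miRNAs alone the share lay that far above in 5 of 7 libraries, but not in 5 (ratio 0.731) and 7 (ratio 1.4). Carry-over of cells therefore stays open, and so does release by living cells, which was not tested.

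In allergic lavage cells, changes in both directions could come from depth, from fewer epithelial cells per pellet, or from the cells recruited by the allergen. With every library thinned to the lowest total, 75 of the 122 called miRNAs kept their call and sign, which argues against depth. If epithelial cells were diluted, miRNAs higher in brushings than in pellets should fall, and Spearman's rho of the pellet change with that ratio was -0.224 over 216 miRNAs. Of the 58 lower miRNAs 30 were higher in brushings than in pellets, and of 63 higher miRNAs 19 were. The rho lies between the values set for and against dilution. The non-allergic pellet level is the denominator of both the change and the ratio, so its error alone pushes rho upward. The rho therefore cannot decide, dilution stays open, and recruitment of cells was not tested.

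The chromosome X cluster of miR-322 to miR-450, lower in allergic than in untreated mice, could reflect a single untreated library, the challenge, immunization or age, or the library sets. Without any 1 untreated library the median change was at most log2 -2.93 in fluid and -1.25 in serum, which argues against a single library. Allergic against immunized mice gave medians of log2 -0.303 in fluid, 0.429 in serum and -0.526 in cells, with all 8 members below 0 in cells. Those values are from sets 3 and 4, and set 2, where the drop was measured, held no immunized library. In sets 3 and 4 a challenge effect as large as that drop was thus not seen in fluid or serum. The challenge stays open for set 2 and in cells. For immunized against untreated mice, the allergic libraries of set 2 lay below those of sets 3 and 4 by a median of log2 -1.34 in fluid and -1.05 in serum. Without the link through them, immunized minus untreated was log2 -1.48 in fluid, where a set difference stays open, and -0.231 in serum, so that the serum difference rests on that link. Immunization and age were not tested and stay open.

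The number of calls was compared with that of other splits of the same libraries. Given here are the splits with as many calls as the real grouping (the real one included) out of those fitted. Where 100 were fitted, here and in the next paragraph, the others were drawn at random from more possible splits. The highest other count is then that of the drawn splits only. For allergic against non-allergic mice this was 1 of 100 in fluid (84 called, at most 62 otherwise, with immunized library 2 and allergic library 5 of set 3 exchanged), 1 of 100 in cells (122, at most 73 otherwise, with the same exchange) and 100 of 100 in serum (0, at most 3 otherwise). In brushings (9 called, at most 3 otherwise, 1 of 10) and for allergic against untreated mice in fluid (83, at most 0, 1 of 10), cells (102, at most 4, 1 of 10) and serum (38, at most 3, 1 of 10) there were too few splits to tell. Allergic against immunized gave 2 of 34 in fluid (16 called, at most 23 otherwise, with immunized library 1 and allergic library 7 exchanged), where chance is not excluded, 1 of 34 in cells (99, at most 1 otherwise) and 34 of 34 in serum (0, at most 4 otherwise). Immunized against untreated gave 3 of 35 in fluid (3, at most 6 otherwise), 4 of 35 in cells (2, at most 2 otherwise) and 1 of 35 in serum (13, at most 3 otherwise). Only the real grouping keeps these groups in separate sets, while every other split places both labels in a shared set. The splits are thus unlike the real grouping, and chance is not excluded in any of the 3.

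For the compartments in non-allergic mice, splits with as many calls were 1 of 100 against serum (274, at most 172 otherwise), 1 of 100 against lavage cells (243, at most 115 otherwise) and 1 of 100 against brushings (40, at most 9 otherwise). For the difference of the allergic change between fluid and another compartment they were 3 of 100 for serum (26, at most 28 otherwise, with the fluid libraries in their real groups), 1 of 100 for lavage cells (68, at most 63 otherwise) and 100 of 100 for brushings (0, at most 1 otherwise).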

How the results depend on the processing

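The counts of calls below are those that moved by more than 1.5 times, and the cause was not tested unless it is given. Without the filter on low counts, allergic against non-allergic brushings had 16 calls, allergic against immunized fluid 29, immunized against untreated fluid 24 and cells 8, and the fluid-brushings difference 14. DESeq2 called 31 for allergic against immunized fluid, 17, 9 and 27 for immunized against untreated fluid, cells and serum, 44 for the fluid-serum difference and 1 for the fluid-brushings difference. Total count scaling gave 20 for allergic and 8 for immunized against untreated serum. Without the set term there were 0 calls in brushings, 32 for allergic against immunized fluid, and 16 and 26 for immunized against untreated fluid and serum; miR-202-5p in serum turned to log2 0.973 for allergic and 0.999 for immunized against untreated mice. limma on deposited RPM values called 4 in brushings, 15 for allergic against untreated serum, and 0 and 6 for immunized against untreated cells and serum.

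Same-numbered libraries were tested for pairing: fluid and cells correlated at 0.038 to 0.29 (7 of 14 pairs above 0.1), fluid and serum at -0.149 to 0.204 (1 of 14), and cells and serum at -0.171 to 0.2 (3 of 14). The correlations are of deviations from the mean of a group within its set. In sets 3 and 4 the 2 libraries of a group mirror each other, so each value there appears under both. The pairs are thus not all separate, and all values of fluid with cells were above 0. Untreated and allergic libraries of a compartment had 1 of 3, 1 of 3 and 0 of 3 pairs above 0.1 in fluid, cells and serum, and immunized and allergic libraries 0 of 4, 0 of 4 and 1 of 4. The numbers were therefore not used within a compartment. Whether fluid and cells of the same number came from the same mouse stays open. With the replicate block, which leaves fewer degrees of freedom, calls were 21 in serum and 0 in brushings for allergic against non-allergic mice, 45 for allergic against untreated fluid, 0 in fluid and 0 in cells for allergic against immunized mice, 0, 0 and 0 in fluid, cells and serum for immunized against untreated mice, 20 for fluid against brushings and 4 for the fluid-brushings difference. The block turned serum shares to log2 -0.2715 (hematopoietic), -0.422 (epithelial) and 0.1124 (erythroid), and miR-497a-3p in the fluid-brushings difference to log2 5.88; it changed no other count by that much.

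Among alternatives chosen after seeing the data, brushings of sets 3 and 4 alone had 0 calls (fewer libraries), the miR-451a covariate left 50 in fluid (24 higher, 26 lower) and 1 in serum, and thinning left 78 in cells. The erythroid share of fluid, log2 1.611, passed when permuted over all libraries (exact permutation p = 0.039), and likeness of fluid to brushings with a non-allergic reference was -0.02311 (exact permutation p = 0.0333). With an estimated correlation the called lists went from 17 to 0.

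Leaving out 1 library gave, for allergic against non-allergic mice, 61 to 91 calls in fluid, 114 to 128 in cells, 0 in serum and 0 to 27 in brushings. For allergic against untreated mice it gave 50 to 97, 78 to 114 and 17 to 56 in fluid, cells and serum, for allergic against immunized mice 0 to 29, 66 to 105 and 0, and for immunized against untreated mice 0 to 15, 0 to 9 and 7 to 22. Fluid differed from serum in 260 to 287, from cells in 228 to 251 and from brushings in 17 to 45, and the differences of the allergic change had 17 to 35, 53 to 70 and 0 to 2. Shares ranged as log2 1.229 to 1.479, 1.496 to 1.791 and 0.006183 to 0.348 (hematopoietic in fluid, cells and serum), -0.2321 to -0.04793, -2.037 to -1.63 and -0.3142 to 0.2426 (epithelial) and 1.175 to 1.932, -0.5291 to 0.1031 and -0.2697 to -0.04745 (erythroid). Signs turned for the epithelial share of serum (-0.1871, -0.03688, -0.08138, -0.3142, -0.03656, -0.1521, -0.1167) and the erythroid share of cells (0.04941, 0.03607, 0.097, 0.1031). Likeness differences were 0.03263 to 0.04437 (cells), -0.02055 to -0.01016 (brushings) and 0.002141 to 0.01455 (serum).

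Named miRNAs kept direction and call in 2204 of their alternative values, while 280 lost and 9 gained a call and 3 turned; with a library left out these were 7839, 610, 5 and 0. Total count scaling, the RPM values and the set term were not varied for comparisons between compartments. At 3 counts per library, cell miRNAs below 69.6 CPM in the shallowest library could not be told from 0.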

Other observations

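Fluid and brushings had fold changes that went together in allergic mice. Across 247 miRNAs tested in both, Pearson's r was 0.662 and Spearman's rho 0.524. Of 8 miRNAs called in both, 7 were higher in both, against 1.36 for independent lists of these sizes, and 1 was lower in both, against 0.138. Fluid and serum had a Pearson r of 0.267 over 234 miRNAs, cells and serum 0.199 over 201, and cells and brushings 0.347 over 199. These are across miRNAs, which are not independent replicates.

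Of lists whose shares were tested outside the plan, and so chosen after the data were seen, the mesenchymal and muscle list took 0.76% ± 0.252 of the counts in 7 allergic and 1.87% ± 0.931 in 7 non-allergic fluid libraries (log2 -1.21, exact permutation p = 0.00556; -1.49, -0.56 and -1.44 within sets 2, 3 and 4). The multiciliated share of cells was 0.212% ± 0.0797 against 0.87% ± 0.333 (log2 -2.04, exact permutation p = 0.00278; -2.45, -1.49 and -1.99 within sets), and in fluid 5.93% ± 1.63 against 5.12% ± 1.02 (log2 0.19, exact permutation p = 0.375). The endothelial share of fluid was 0.102% ± 0.0362 against 0.306% ± 0.218 (log2 -1.37, exact permutation p = 0.00278; -2.12, -1.03 and -0.605 within sets). In brushings the smallest p possible was 0.25, and the erythroid share of 6.96% ± 8.82 in 3 allergic and 0.392% ± 0.298 in 3 non-allergic libraries had that value.

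Untreated serum library 1 had a mean Spearman correlation of 0.873 with the other serum libraries, which had at least 0.921.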
